A study of Rattus norvegicus with 14 samples.

How the data were processed

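Total RNA from microdissected dentate gyrus of 14 rats, 7 per group, was labelled with biotin and hybridised to Affymetrix RAE230A arrays, 1 array per rat, per the labels' protocols. CA1 and CA3 were dissected as well, and are not analysed here. Groups and replicate numbers came from the sample titles, which call the arrays biological replicates. The labels give no batch, slide or scan date.

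The deposited values are log2 expression values per probe set, made with GCRMA per the submitters' processing notes. The version of GCRMA and its settings are not given in the sources used here. GCRMA corrects the background from probe sequence, normalizes arrays to a common distribution and summarises the probes of a probe set, and it compresses differences of probe sets near background. The log2 scale was read from the deposited values, which ran from -0.56 to 15.0 with array medians of 5.09 to 5.12. Probe-level intensities were not used here.

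The table holds 15923 probe sets, of which 57 are controls. Of the other 15866, 12783 have 1 gene symbol in the platform annotation, 312 have several and 2771 have none listed. Gene IDs of 12754 single-symbol probe sets matched the current rat gene table (assembly GRCr8), and 0 symbols changed. No coordinates were used, since the probe sets' genome build is not given in the sources used here. Probe sets with a mean of at least 4 over the 14 arrays were tested, without controls: 9387 passed and 6479 did not. Of those tested, 7796 had 1 symbol, which gave 6697 genes. A gene was represented by its probe set of highest mean. For genes named by the rule below, probe sets of opposite sign are given in the text, and weaker ones of the same sign for some genes.

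Learning minus control was fitted with limma 3.58.1 (lmFit and eBayes, default prior) in R 4.3.3, with no covariate and a Benjamini-Hochberg adjusted p of 0.05 as threshold. The prior had 3.18 degrees of freedom, and the median standard error of a difference was 0.08 log2 units. The number of arrays limits the precision. Simulated data had probe sets drawn independently, with 200 of 9387 changed, in 20 runs per size. The share of false calls was 4.58% at 0.25 log2 units, 5.88% at 0.5 and 5.61% at 1.

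Before the data were examined, 16 gene lists and 14 marker lists were fixed. Their names are activity-regulated transcription factors, activity-regulated effectors, glutamate receptors, GABA receptors and synthesis, postsynaptic scaffold and kinase genes, presynaptic vesicle genes, cAMP and MAP kinase signalling, neurotrophins and growth factors, voltage-gated channels, glucocorticoid-responsive genes, chaperones, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, the clock and neurogenesis. The marker lists cover granule, CA3, CA1 and mossy cells, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, choroid plexus, meninges, blood and thalamus. Lists with at least 3 measured members were tested with limma's fry, 1 probe set per gene, adjusted over the 16 gene lists or the 12 marker lists tested. Fry's directional p asks whether members move on balance one way, and does not compare the list with other genes. In 20 simulated runs with genes drawn independently and no change, 6.88% of directional p values were below 0.05. A shift of 0.15 log2 units in the activity-regulated effectors was called in 20 runs.

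The genes named in the text were set by a rule fixed at the same time. It takes 12 genes per direction, first those past the threshold and then those of smallest unadjusted p, 3 genes of smallest p per gene list, 2 genes of highest mean per marker list, and Arc, Fos, Egr1, Homer1, Bdnf, Nr4a1, Junb, Fosb, Gria1, Grin1, Camk2a and Prox1. Since no probe set passed the threshold, the first part of the rule rests on unadjusted p. Bok, Cadm1, Elavl4, Dsp, C1qc, P2ry12, C1qb, the CA1 marker Wfs1 and the unnamed probe set fall outside the rule. They were chosen after their values were seen. Igfbp2, Slc6a20a, Col1a1, Vim and Dcn also fall outside it, and are named as leading genes of a component or as list members.

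Alternatives planned in advance were other filters, quantile normalization, median centring, a trended robust prior, array weights, the replicate number as a block, a floor at 3, leaving out probe sets ending in _s_at or _x_at, camera with an estimated or preset correlation, the mean of all probe sets of a gene, and each array left out in turn. Covariate fits with the meningeal marker mean, the CA1 marker mean or the 3' minus 5' difference of the beta-actin control probe sets were added after the data had been seen. Single values per array were compared with two-sided exact permutation tests over all assignments of the 14 arrays to groups of 7, whose smallest p is 0.000583. Figures were drawn with matplotlib 3.10.9.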

Results

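Gene expression was measured in the dentate gyrus, the part of the hippocampus whose granule cells receive the main cortical input, of 14 young male Long-Evans rats aged 3 to 4 months. The rats had learned a standard water maze, a pool in which a rat swims to an escape platform, 2 to 3 weeks earlier. Each rat then had 1 session of 8 trials in a pool at another site. For the 7 learning rats the visible platform kept its place and spatial cues were present. For the 7 control rats the platform moved between trials and the surroundings gave no useful cues. A probe swim of 90 s followed 1 h after the session, and tissue was collected straight after it. RNA of each rat was hybridised to 1 short-oligonucleotide array, so the 14 arrays are 7 biological replicates per group. The comparison asks which dentate gyrus transcripts differ after a session in which new spatial information could be learned. Array medians lay between 5.09 and 5.12 on the log2 scale. The correlation between any pair of arrays lay between 0.995 and 0.998 across all probe sets other than controls, tested or not.

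The gene with the largest difference was Ttr, which encodes transthyretin, a carrier of thyroid hormone made in large amounts by the choroid plexus. Its level was 7.47 ± 1.07 on the log2 scale in control rats (SD, n = 7) and 5.68 ± 0.14 in learning rats (SD, n = 7). This is 3.44-fold higher in control tissue, and every control array lay above every learning array. Tmpo, which encodes a protein of the inner nuclear membrane, had the smallest p of all probe sets and was higher in learning rats by 0.52 ± 0.08 log2 units (SE), or 1.43-fold, again with no overlap between the groups. Rapgef4, which encodes the cAMP-activated exchange factor Epac2, was lower in learning rats by a difference of -0.63 ± 0.12 (SE). None of these differences passed adjustment over all probe sets: in limma's moderated test the adjusted p was 0.153 for Ttr, 0.152 for Tmpo and 0.153 for Rapgef4.

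Across 9387 tested probe sets, limma called 0 at an adjusted p below 0.05, 0 below 0.10, and 1230 at an unadjusted p below 0.05, where 469 would be expected by chance. At an unadjusted p below 0.01 there were 369 probe sets, 177 higher and 192 lower in learning rats, against 93.9 expected by chance, a ratio of 3.93. The groups did not overlap for 38 probe sets, 16 higher and 22 lower in learning rats. Chance gives a share of 0.0583%, or 5.47 probe sets, which is a mean over regroupings of the arrays. Single regroupings can lie far above such a mean. Of 100 regroupings, only the real one gave as many as 38, and the highest other gave 25. At an unadjusted p below 0.01 the highest other regrouping gave 365, and the median of the others was 54. The ratio of 3.93 therefore does not show how far the real groups stand out. Differences were small: the median absolute difference was 0.08 log2 units, the 95th percentile 0.29, and 40 probe sets differed by at least 0.5. In simulated data of the same size and spread, 18.2% of changes of 0.25 log2 units (1.19-fold) were recovered, 78.9% of changes of 0.5 (1.41-fold) and 98.4% of changes of 1 (2-fold). The simulation drew each probe set independently and changed 200 at once. Its shares may not hold for the real arrays, whose probe sets vary together. The count at an unadjusted p below 0.01 was 224 without control replicate 2, 237 without control replicate 4 and 239 without learning replicate 7. The count past the adjusted threshold became 1 without control replicate 6, without learning replicate 1 or without learning replicate 4, with a different probe set each time. These were a probe set with no gene name in the annotation used here, Ripor2 and Tmpo.

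The 12 genes of smallest p that were higher in learning rats included Tmpo. Tug1, a long non-coding RNA, was higher by 0.41 ± 0.08 log2 units (SE), Ranbp2, a nuclear pore protein, by 0.40 ± 0.09 (SE), and Zfp422, a zinc finger protein, by 0.39 ± 0.09 (SE). Larp4b, an RNA-binding protein, was higher by 0.33 ± 0.06 (SE), although its second probe set differed by -0.27. The other members were Mmd at 0.33, Rfng, a glycosyltransferase that modifies Notch, at 0.44, Dpp8 at 0.33, Spcs3, a signal peptidase subunit, at 0.31, Tmem47 at 0.49, and Kif3b, a kinesin motor, at 0.32. Second probe sets of Rfng and Dpp8 differed by 0.12 and 0.13. Atp2a2, which encodes the calcium pump SERCA2, was higher by 0.21 on its brightest probe set, while its other probe sets differed by -0.02 and -0.19. Apart from Tmpo, all of these genes had adjusted p values of 0.153 in limma.

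Ttr and Rapgef4 headed the 12 genes of smallest p that were lower in learning rats by size of difference. Among the others, Dlgap4, a scaffold protein of the postsynaptic density, differed by -0.37 ± 0.08 (SE), and Rab3a, a GTPase of synaptic vesicles, by -0.21 ± 0.05 (SE). Ckap5, a microtubule polymerase, differed by -0.46, and Actr1b, a subunit of dynactin, by -0.49 with +0.05 on its other probe set. Ripor2, a regulator of RhoA, differed by -0.44, Tsr2, which acts in ribosome assembly, by -0.46 with 0.06 on its other probe set, and Psmb2, a proteasome subunit, by -0.33. Pdcd10, the gene of a familial cerebral cavernous malformation, and Pcnx4 both differed by -0.30, and the uncharacterised LOC102547703 by -0.41. Their adjusted p values in limma lay between 0.153 and 0.155.

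**Figure D1:**
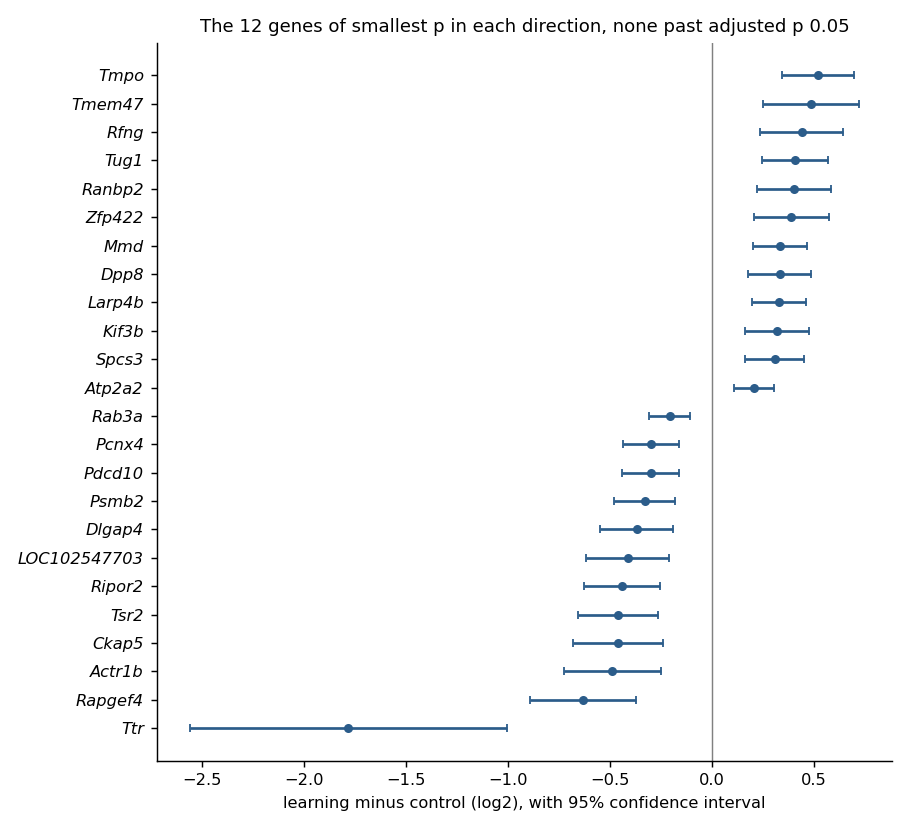
Learning minus control difference in log2 units for the 12 genes of smallest p in each direction; points are limma estimates and bars 95% confidence intervals from 7 rats per group. Ttr lies at -1.78, and the other 23 genes lie between -0.63 and 0.52.

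Among classical activity-regulated transcripts, Arc, Egr1, Fos, Fosb, Junb, Nr4a1 and Bdnf differed by at most 0.12 log2 units between the groups. Over the full lists of activity-regulated transcription factors and effectors, the median absolute difference was also 0.12, so many members differed by more. Arc, an immediate-early gene whose product acts at synapses, was at 7.88 ± 0.23 in control rats (SD, n = 7) and 7.93 ± 0.14 in learning rats (SD, n = 7), a difference of 0.05 with a 95% confidence interval from -0.15 to 0.25. Egr1, a transcription factor induced by activity, differed by 0.12 ± 0.10 (SE), Fos by -0.12 ± 0.13 (SE), Fosb by -0.03, Junb by 0.10 and Nr4a1 by -0.04. Fos averaged 4.60 in control and 4.47 in learning rats, near the filter level of 4. Fosb averaged 5.25 and 5.22, near the array medians. GCRMA compresses differences near background, so the small differences of Fos and Fosb say little. Bdnf, a neurotrophin released with activity, differed by 0.07 ± 0.16 (SE). None of these 7 genes had an adjusted p below 0.594 in limma, and such small values depended on single rats: Egr1 was at 0.06 without control replicate 2, Fos at -0.05 without control replicate 1, and Junb and Fosb at 0.03 and -0.0005 without learning replicate 5. Homer1, a scaffold of metabotropic glutamate receptors, was higher in learning rats by 0.25 ± 0.08 (SE), with an unadjusted p of 0.0089 and an adjusted p of 0.242. A second Homer1 probe set differed by 0.30, and the remaining probe sets by 0.10, 0.11 and -0.05.

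Of 17 measured activity-regulated transcription factors, 8 were higher and 9 lower in learning rats. The 3 of smallest p were Crem, a cAMP-response factor, at 0.22, the orphan receptor Nr4a3 at 0.23 and Tiparp at 0.23, and no member passed adjusted over the list alone (lowest adjusted p 0.139). The list's mean difference was -0.0061 and its median -0.03, while fry's direction was up, with an adjusted p of 0.976. Of 20 measured activity-regulated effectors, 11 were higher and 9 lower, with a mean of -0.0031, a median of 0.04 and an adjusted p of 0.976 in fry, whose direction was down. Nrn1, which encodes the neurite-promoting neuritin, differed by -0.22, and Scg2, a secretory granule protein, by -0.14. Fry's mixed test, which asks whether members differ in either direction, gave its lowest adjusted p, 0.0518, for the transcription factors and for the voltage-gated channels.

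**Figure D2:**
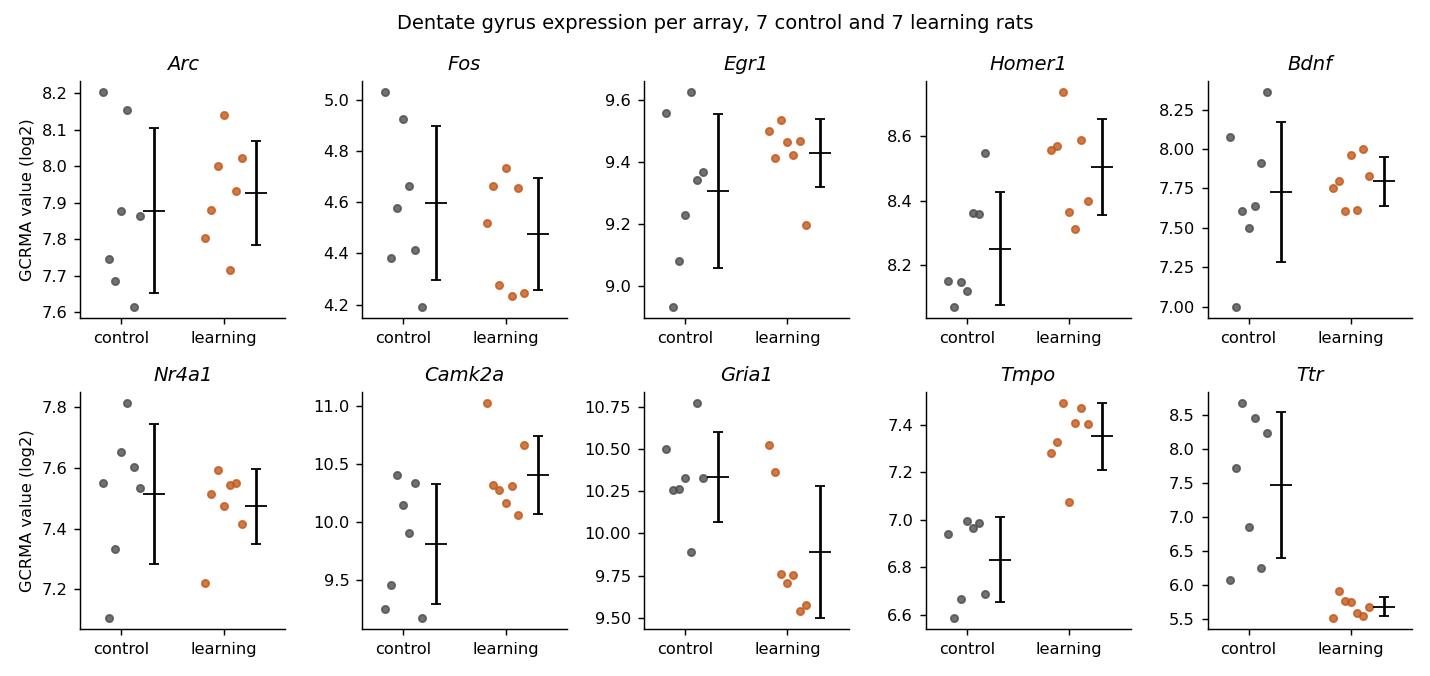
Log2 expression of 10 genes on each of the 14 arrays; dots are rats and the bar beside each group is the mean ± SD, with n = 7 per group. For Arc, Fos, Bdnf and Nr4a1 the learning values lie within the range of the control values, whereas all 7 control values of Ttr (6.07 to 8.68) lie above all 7 learning values (5.52 to 5.92).

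Synaptic genes showed differences of both signs. Camk2a, the alpha subunit of calcium/calmodulin kinase II, was higher in learning rats by 0.59 ± 0.21 (SE; adjusted p = 0.263 in limma), with 0.23 and -0.14 on its other probe sets. Gria1, which encodes the AMPA receptor subunit GluA1, differed by -0.45 ± 0.16 (SE; adjusted p = 0.280 in limma), and Grin1, the obligatory NMDA receptor subunit, by 0.02 ± 0.09 (SE). Of 31 postsynaptic scaffold and kinase genes, 19 were higher and 12 lower; 1 member, Dlgap4, passed adjusted over the list alone (adjusted p = 0.015) and 0 passed over all genes. Dlgap1, its paralog, was higher by 0.24 on its brightest probe set and differed by -0.14 and 0.02 on the others. Of 29 presynaptic vesicle genes, 15 were higher and 14 lower. Rab3a passed adjusted over that list alone (adjusted p = 0.0156), and Pclo, a scaffold of the active zone, was higher by 0.45 while Nsf, the ATPase that recycles fusion complexes, differed by -0.13.

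Glutamate receptor genes numbered 16, with 9 higher and 7 lower, among them Cacng2, which encodes the AMPA receptor auxiliary subunit stargazin, at 0.31 and Grik4 at 0.13 (0.08 without learning replicate 6). A second Cacng2 probe set differed by 0.04. Of 10 GABA receptor and synthesis genes, 5 were higher and 5 lower, with Gabrb2 at 0.24, Gabrb1 at -0.17 (-0.09 without learning replicate 3) and Gabra4 at 0.20. Of 24 voltage-gated potassium and sodium channel genes, 15 were higher. The sodium channel genes Scn2a and Scn3a were higher in learning rats by 0.41 ± 0.11 (SE) and 0.69 ± 0.24 (SE), and the inward rectifier Kcnj4 differed by -0.24 on one probe set and -0.40 on the other. Fry gave adjusted p values of 0.952 for the glutamate receptors and the postsynaptic genes, 0.976 for the GABA and presynaptic genes and 0.682 for the channels. The presynaptic genes had a mean of 0.0042, while fry's direction was down.

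Neurotrophins and growth factors had the smallest directional p of the 16 gene lists. Of 15 measured members, 3 were higher and 12 lower in learning rats, with a mean difference of -0.14, or -0.11 with the meningeal marker mean as covariate (adjusted p = 0.127). The list mean was the highest of its group in control replicate 5 (6.94) and learning replicate 4 (6.84), where meningeal markers were high too (7.10 and 7.49). Nbl1, a secreted BMP antagonist, differed by -0.40 ± 0.14 (SE), Ntf3, which encodes neurotrophin-3, by -0.28 ± 0.12 (SE) and Tgfb2 by -0.19 ± 0.09 (SE), although the value was -0.11 without control replicate 2 and a second Tgfb2 probe set differed by 0.19. Igf2, also a meningeal gene, differed by -0.49 ± 0.73 (SE), and by -0.94 without learning replicate 4 and -0.12 without control replicate 3. A second Igf2 probe set differed by 0.09. The list's directional p in fry was 0.00902 and its adjusted p 0.144, and with an estimated correlation camera gave p = 0.0365 (adjusted p = 0.584). The adjusted p was 0.0378 with all probe sets of a gene averaged, 0.006 with the CA1 marker mean as covariate, 0.0343 without control replicate 6 and 0.989 with no filter on low values, where the mean difference was -0.06, the highest of its 24 alternatives.

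Glucocorticoid-responsive genes came next: 11 of 16 were lower in learning rats, with a mean of -0.09 and an adjusted p of 0.440 in fry. Ddit4, a stress-induced inhibitor of mTORC1, differed by -0.25 ± 0.08 (SE), Il6r by -0.35 and Errfi1 by -0.22. Of 23 cAMP and MAP kinase genes, 11 were higher and 12 lower, including the phosphodiesterase gene Pde10a at 0.33, Atf2 at 0.44 and Gnas, the stimulatory G protein, at -0.13. Of 33 chaperone genes, 16 were higher and 17 lower; Canx, which encodes calnexin, was higher by 0.32 and passed adjusted over the list alone (adjusted p = 0.033), but its other probe sets differed by 0.04 and 0.02. Hspa1a, the inducible HSP70, differed by -0.32 and Dnajb9 by -0.14. The adjusted p in fry was 0.952 for the cAMP and MAP kinase genes, whose mean was 0.03 and median -0.01, and 0.976 for the chaperones, whose mean was 0.01 and median -0.01.

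Housekeeping and developmental lists showed differences of a few hundredths of a log2 unit. Of 60 oxidative phosphorylation genes, 31 were higher and 29 lower, with Ndufs8, a complex I subunit, at -0.34, Cox6b1 at -0.17 and Cox6a1 at -0.15; the mean was -0.01, the median 0.0059 and the adjusted p 0.976. Of 39 cytosolic ribosomal protein genes, 23 were higher, with Rpl5 and Rpl7a both at 0.14 and Rps28 at 0.12, and an adjusted p of 0.682. Of 17 cholesterol synthesis genes, 8 were higher and 9 lower, with squalene epoxidase (Sqle) at -0.29, Msmo1 at 0.12 and Nsdhl at 0.24, and an adjusted p of 0.952. Of 12 clock genes, 6 were higher and 6 lower, with Nr1d2 at 0.13 (0.08 without control replicate 1), Bhlhe41 at -0.11 (-0.06 without control replicate 5) and Per2 at -0.14 (-0.06 without control replicate 6), and an adjusted p of 0.976. Neurogenesis genes were split 7 and 7, with Ccnd2, a cyclin of neural progenitors, at -0.31, Ncam1 at -0.16 and Stmn2 at 0.17, and an adjusted p of 0.952. A second Stmn2 probe set differed by 0.0011. All of these p values are from fry over 16 lists.

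**Figure D3:**
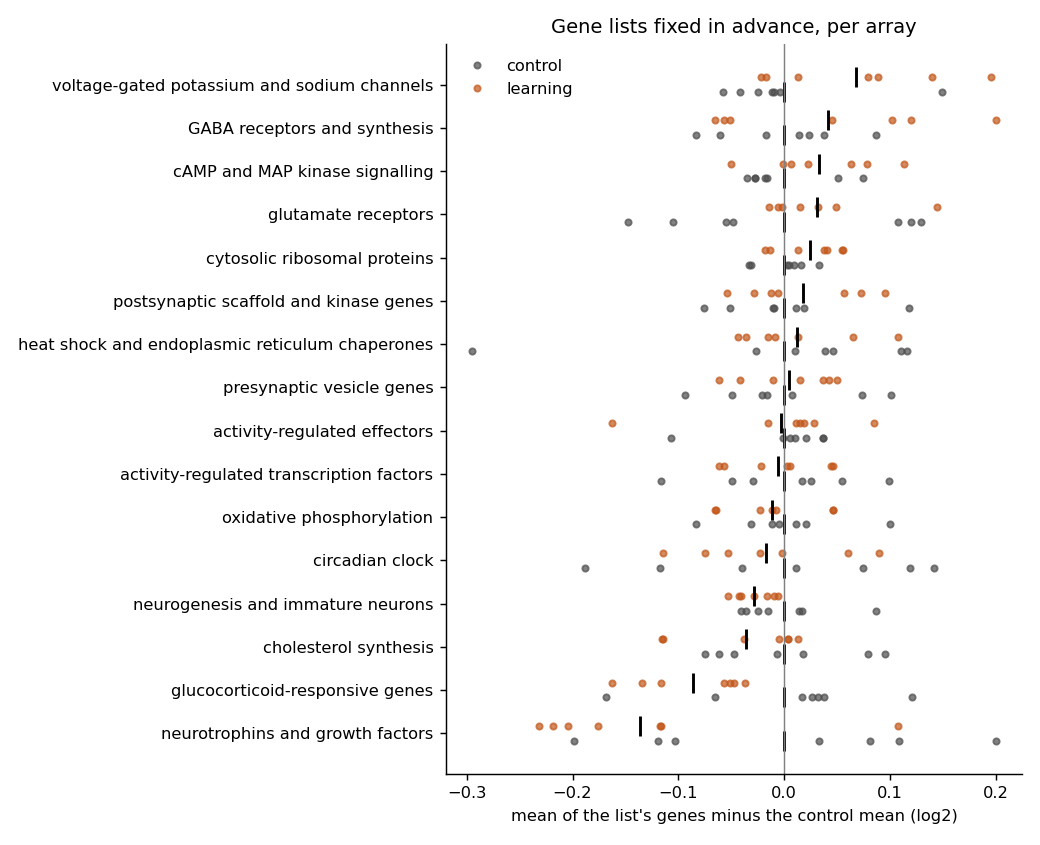
Mean log2 expression of each of the 16 gene lists per array, relative to the mean of the control arrays; dots are rats (7 control, 7 learning) and black ticks group means. The groups overlap in every list, and neurotrophins and growth factors have the lowest learning mean, at -0.14.

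Markers of the dissected and neighbouring tissue were compared in the same way. Prox1, the transcription factor that marks dentate granule cells, was at 10.3 ± 0.25 in control rats (SD, n = 7) and 10.3 ± 0.17 in learning rats (SD, n = 7). The 7 granule cell markers had a mean difference of 0.11 (adjusted p = 0.431 in fry over 12 marker lists), with Calb1, the calcium-binding protein calbindin, at -0.03. The 8 CA1 markers were higher by 0.23 on average (adjusted p = 0.431), with Itpka at -0.05 and Lmo3 at 0.0025. Without control replicate 5, whose CA1 marker mean of 7.23 was the highest of all arrays, the CA1 difference was 0.35 and its adjusted p 0.0216, the lowest of 23 alternatives that reached up to 0.677. Leaving out the highest control array by itself widens this difference, so that p value is no independent test of it. The 6 CA3 markers were split 3 and 3 (adjusted p = 0.841); 4 of them passed adjusted over the list alone, with Chgb and Bok higher by 0.16 and 0.29 and Cadm1 and Elavl4 at -0.27 each.

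The other marker lists did not pass fry's test either. The 5 choroid plexus markers averaged -0.61 (adjusted p = 0.431), or -0.26 with no filter on low values, of which Ttr alone passed adjusted over the list alone (adjusted p = 0.000949), while Enpp2 differed by -0.04. The 7 meningeal and fibroblast markers averaged -0.29 (adjusted p = 0.841) with a wide spread within both groups: 5.84 ± 1.14 in control rats (SD, n = 7) and 5.54 ± 1.18 in learning rats (SD, n = 7). Their difference was -0.67 without learning replicate 4 and -0.08 without control replicate 5. Ptgds, a prostaglandin D synthase made by the leptomeninges, ranged from 8.87 to 13.4 in control rats and from 8.84 to 12.9 in learning rats. Astrocyte markers averaged -0.07 (adjusted p = 0.431), with Apoe at 0.06 and S100b at -0.05, and microglial markers -0.12 (adjusted p = 0.624), with Csf1r at -0.06 (-0.0048 without control replicate 3) and Ctss at -0.02. Interneuron markers averaged 0.07 (adjusted p = 0.650), with Gad1, a GABA-synthesising enzyme, at -0.19 and Cck at 0.09. The other Gad1 probe set differed by 0.08. Oligodendrocyte markers averaged -0.02 (adjusted p = 0.926). Mbp was at 0.11 (0.05 without control replicate 3 and 0.19 without control replicate 1), with -0.05 on its other probe set. Mobp was at -0.16 (-0.07 without control replicate 1). Markers of oligodendrocyte precursors averaged -0.08 (adjusted p = 0.624), with Olig1 at -0.06 and Pdgfra at -0.02. Endothelial markers averaged 0.03 (adjusted p = 0.841), with Cldn5 at -0.10 and Slc2a1 at 0.0047, and blood markers 0.02 (adjusted p = 0.650), with Hbb at -0.03 and S100a8 at 0.09. Without control replicate 4, the microglial mean was -0.08, the precursors' mean -0.05, Cldn5 -0.05 and S100a8 0.04. Hilar mossy cell and thalamic markers had 2 measured members each and were not tested as lists: Cartpt was at -0.04, Ociad2 at -0.16, Tcf7l2 at 0.05 and Prkcd at -0.0039.

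**Figure D4:**
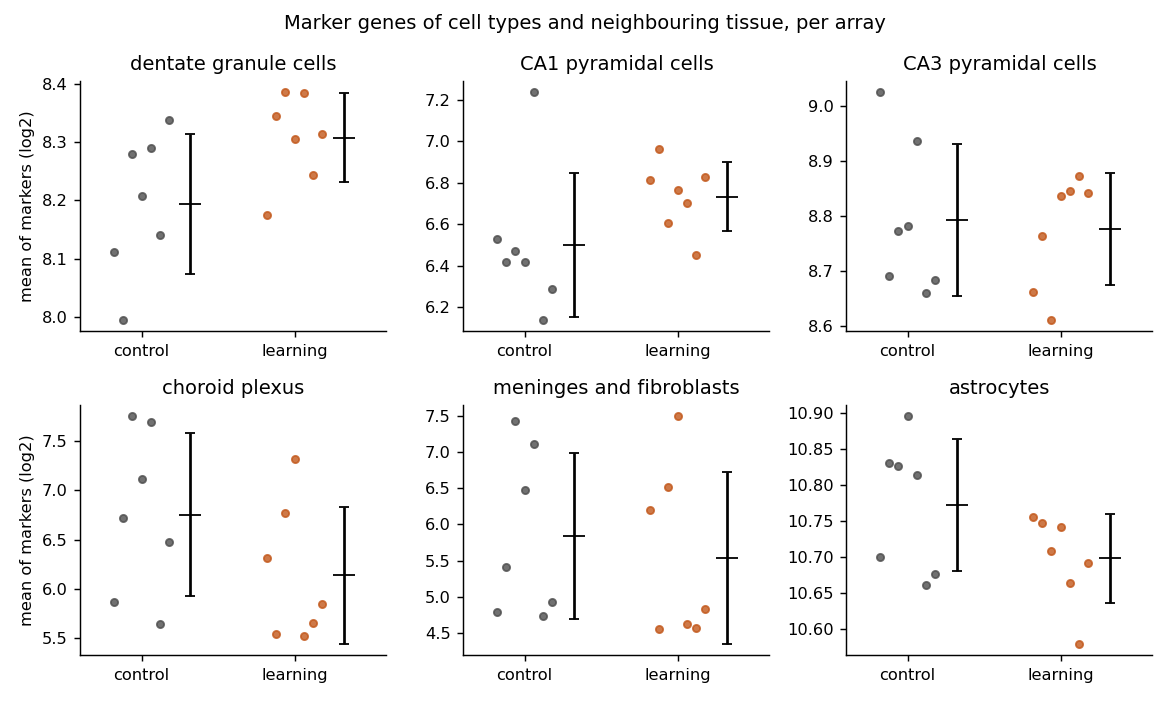
Mean log2 expression of marker genes for 6 cell types or tissues on each array; dots are rats and bars are the mean ± SD, with n = 7 per group. Meningeal markers spread over more than 2 log2 units in both groups, and 1 control array (replicate 5) stands above the rest for CA1 markers, at 7.23.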

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

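The test of meninges as a source of the Ttr difference, the choroid plexus mean without Igfbp2, all tests of Wfs1 and all covariate fits were chosen after the results they bear on, or the data, had been seen.

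Ttr was lower on all 7 learning arrays (5.52 to 5.92) than on all 7 control arrays (6.07 to 8.68). Choroid plexus tissue carried into control dissections may account for this, since Ttr is among its most abundant transcripts, but the mean of 10 other choroid plexus markers was 0.0796 log2 units higher in control arrays (exact permutation p = 0.424), and 0.00732 without Igfbp2 (exact permutation p = 0.463), which carries most of that value and is among the leading genes of the component led by meningeal transcripts. Most of those markers had means below the filter level of 4, so this leaves the source open. With the meningeal marker mean as covariate the Ttr difference was -1.69 (95% limits -2.41 and -0.97). That fit could remove little, since the meningeal mean differed by only -0.29 between the groups. In control replicates 3 and 5 Ttr (8.68 and 8.45) and the meningeal mean (7.42 and 7.10) were both high. Both were low in control replicates 1 and 6, but control replicate 7 had Ttr at 8.23 with a mean of 4.94. Learning replicates 3 and 4 had meningeal means of 6.51 and 7.49 and Ttr at only 5.78 and 5.76. These learning values argue against meningeal tissue as the whole source, and a part in the control arrays stays open. An effect of the task itself stays open as well, and was not tested apart from dissection.

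The CA1 marker list did not pass its test (fry adjusted p = 0.431; 6 members higher and 2, Dcn and Itpka, lower in learning arrays, with 0 passing adjusted over the list alone), and its largest difference was in Wfs1: 6.84 ± 1.07 in control arrays (SD, n = 7) and 7.79 ± 0.38 in learning arrays (SD, n = 7; exact permutation p = 0.0478, adjusted p = 0.342 over 8 markers). Within groups, Wfs1 deviated together with the mean of 6 other CA1 markers (Pearson r = 0.852, permutation p = 0.00035; Spearman rho = 0.754, permutation p = 0.00208), with r = 0.663 without the 2 arrays farthest from the median and 0.652 without control replicate 5. This is consistent with dissections that held different amounts of CA1. Control replicate 5 had Wfs1 at 8.90, and without it the Wfs1 difference was 1.30 (exact permutation p = 0.00117, adjusted p = 0.00932 over 8 markers). That array held the highest control value of Wfs1, and leaving it out by itself widens the difference. These p values are therefore no independent test of it. Whether the learning dissections as a group held more CA1 remains a hypothesis, and regulation of these genes by the task was not tested apart from it.

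The 369 probe sets at an unadjusted p below 0.01 exceeded the 93.9 expected by chance. Of 100 splits of the 14 arrays, drawn from 1716, 1 gave as many, the real one. This is under the 5% set in advance for this count. The highest other split reached 365, and its sides differed by 0.98 in the meningeal marker mean, against 0.29 in the real split. At an unadjusted p below 0.05 that split gave 1306 probe sets, more than the real 1230. At an adjusted p below 0.05 it gave 1 against 0. Chance is therefore not excluded as the source of the excess. A large meningeal gap did not by itself give a high count, since the split with the largest gap, 1.55, gave 117. The count was 329 with the meningeal mean as covariate, 339 with the beta-actin 3' minus 5' difference and 305 with the CA1 marker mean. Between the groups the meningeal mean (exact permutation p = 0.622), the beta-actin difference (exact permutation p = 0.131) and the CA1 list mean (exact permutation p = 0.140) did not differ clearly. Counts that stay high in such fits weigh only weakly against each as the whole cause of the count. Of the 369 probe sets only 305, 222 and 191 passed in these fits, so which probe sets pass depends on the covariate. An effect of the learning session stays open, as do chance and differences in dissection that these measures miss.

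Of 276 groups of 7 values examined for a sample far from the others, 20 stood out, or 7.25%, where chance gives about 1 in 20. Among genes, the highest sample stood apart for Ckap5 in control replicate 4 (8.80, next 8.43), Csf1r in learning replicate 7 (8.47, next 8.17), Fosb in learning replicate 2 (5.64, next 5.19), Per2 in control replicate 6 (8.60, next 8.19) and Tcf7l2 in learning replicate 2 (5.21). The lowest sample stood apart for Egr1 in learning replicate 7 (9.20, next 9.41), Gabrb1 in learning replicate 3 (8.75, next 9.13), Junb in control replicate 3 (6.92, next 7.21), Lmo3 in control replicate 1 (8.09, next 8.39), Nr4a3 in control replicate 2 (7.83, next 8.16), S100a8 in control replicate 4 (4.30, next 4.62) and Tcf7l2 in control replicate 7 (4.68, next 5.08). Among list means, the activity-regulated effectors were low in control replicate 2 (8.29) and learning replicate 5 (8.23), the glutamate receptors high in learning replicate 1 (8.47), the neurotrophins and growth factors high in learning replicate 4 (6.84), and the CA1 markers high in control replicate 5 (7.23). In control replicate 7 the voltage-gated channels were high (7.45) and the chaperones low (8.31), and in control replicate 1 the blood markers were low (6.600).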

How the results depend on the processing

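The covariate fits were chosen after the data had been seen. Limma called 0 probe sets at an adjusted p below 0.05 in every alternative except 3 with 1 array left out, with counts from 0 to 1. At an unadjusted p below 0.01 the count ran from 305 with the CA1 covariate to 443 with array weights, against 369; 323 of the 369 were shared without a filter, 222 with the beta-actin covariate (141 higher, 198 lower in all) and 191 with the CA1 covariate. The floor at 3 gave the same 369 and so tests little. With 1 array left out the count ran from 224 to 432, the higher probe sets from 107 to 205 and the lower from 112 to 229 and the cause was not tested; those that moved it by over 1.5 times were control replicates 2 (224) and 4 (237) and learning replicate 7 (239). Replicate numbers were not taken to pair the rats, since the labels tie them to nothing shared. Same-numbered pairs correlated from -0.28 to 0.26, 4 of 7 above 0.1. Of 7 control arrays, 4 were closest to their own number, more than random numbering gives on average, so pairing is not excluded. The main fit and the exact permutation tests leave any such pairing out. The replicate block gave 0 probe sets at the adjusted threshold, 413 at an unadjusted p below 0.01 and 1330 below 0.05. Of the 369 probe sets, 267 were among the 413. No list or named gene passed with or without the block, which turned the direction of the presynaptic list (mean 0.0042).

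The neurotrophin list became significant at -0.105 with all probe sets of a gene averaged and at -0.189 with the CA1 covariate, and was smaller, at -0.0579, without a filter; with 1 array left out it ran from -0.177 to -0.103, past the threshold without control replicate 6. Choroid plexus markers were at -0.256 without a filter, and meningeal markers ran from -0.671 to -0.084 with 1 array left out. CA1 markers ran from 0.171 to 0.354, past the threshold without control replicate 5, the array where they were highest. Among the other lists and named genes none changed its side of the threshold, except Ripor2 without learning replicate 1 and Tmpo without learning replicate 4. Turns of direction were of small values or of fry's direction alone, and the cause was not tested. They were, without a filter, transcription factors (-0.00045), GABA genes (0.0165), clock (-0.000401), endothelium (0.0117) and blood (0.00397); with median centring, effectors (-0.000986); with array weights, Lmo3 (-0.0237), Olig1 (0.00816), Slc2a1 (-0.00685), effectors (0.00782), presynaptic genes (0.0143), oxidative phosphorylation (-0.00073), oligodendrocytes (0.0397) and endothelium (0.00876). With all probe sets averaged they were chaperones (0.00113) and endothelium (0.0261); with the meningeal covariate, Hbb (0.0129), Pdgfra (0.034), Prkcd (0.0297) and effectors (0.000298); with the beta-actin covariate, Fosb (0.0363), Lmo3 (-0.00232) and Olig1 (0.0200). With the CA1 covariate they were Arc (-0.0545), Calb1 (0.00778), Hbb (0.0611), Lmo3 (-0.00172), Slc2a1 (-0.0451), transcription factors (-0.0206), GABA genes (0.0278), presynaptic genes (0.0295), chaperones (-0.00708), clock (0.0124), CA3 markers (-0.079) and endothelium (-0.00637).

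With 1 array left out, the genes that turned ran as follows: Bdnf -0.0547 to 0.173, Cartpt -0.0896 to 0.0145, Ctss -0.0686 to 0.00391, Enpp2 -0.0859 to 0.00244, Grin1 -0.0356 to 0.0811, Hbb -0.142 to 0.0446, Lmo3 -0.0476 to 0.0206, Nr4a1 -0.108 to 0.0101, Olig1 -0.129 to 0.0299, Pdgfra -0.0972 to 0.0359, Prkcd -0.0678 to 0.0601, Slc2a1 -0.0631 to 0.0587 and Tcf7l2 -0.0149 to 0.0651. Lists that turned were transcription factors -0.0256 to 0.0104, effectors -0.0209 to 0.0235, GABA genes 0.0154 to 0.0596, presynaptic genes -0.0114 to 0.021, chaperones -0.0374 to 0.0305, oxidative phosphorylation -0.0253 to 0.00524, clock -0.0483 to 0.00671, CA3 markers -0.0388 to 0.0223, oligodendrocytes -0.0826 to 0.0688 and endothelium -0.00146 to 0.0602. Blood markers ran from -0.0103 to 0.04. Without turning, values that also moved by over 1.5 times were Apoe 0.0363 to 0.0952, Arc 0.00615 to 0.105, Calb1 -0.0487 to -0.00642, Cck 0.0287 to 0.122, Itpka -0.106 to -0.00546, Nnat -0.213 to -0.0853, Prox1 0.0182 to 0.144, Ptgds -1.10 to -0.334, S100b -0.071 to -0.0156, glutamate receptors 0.00644 to 0.0526, postsynaptic genes 0.00471 to 0.0372, cAMP and MAP kinase genes 0.0281 to 0.0544, cholesterol synthesis -0.0486 to -0.0202, neurogenesis -0.035 to -0.0138 and interneurons 0.0524 to 0.116. Others stand in the report; of those, some also moved away from 0, with Fos at -0.19, Fosb at -0.097, Junb at 0.165, Csf1r at -0.121, Cldn5 at -0.153 and precursors at -0.122. Probe sets near background are limited by GCRMA's floor.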

Other observations

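The comparison of spread below was chosen after values had been seen; the test of activity-regulated genes was set before its correlations were computed.

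Meningeal transcripts led the variation between arrays. The first principal component held 20.1% of the variance, and its leading genes were Ptgds, Igfbp2, Slc6a20a, Igf2, Col1a1 and Vim, with Ttr the seventh. Its absolute correlation with the meningeal marker mean was 0.73, so it held other variation as well. Ptgds was at 13.4 and 13.3 in control replicates 3 and 5 and at 12.9 and 12.7 in learning replicates 3 and 4, but at 8.87 in control replicate 6 and 8.84 in learning replicate 5. Igf2, an imprinted growth factor of the meninges and choroid plexus, ran from 5.89 to 9.89 in control rats. Between the groups this component did not pass (exact permutation p = 0.0385, adjusted p = 0.090 over 3 components), nor did the meningeal marker mean (exact permutation p = 0.622).

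Complement and microglial genes and granule cell genes outside the naming rule were also examined, and chosen after their values were seen. Dsp, which encodes desmoplakin and marks granule cells, was higher by 0.44 ± 0.15 (SE) in learning rats. No granule cell marker passed adjusted over its list alone (lowest adjusted p 0.0699 in limma). C1qc, a complement subunit, differed by -0.29 ± 0.12 (SE), P2ry12, a purinergic receptor of microglia, by -0.33 ± 0.17 (SE), and C1qb by 0.04. The microglial list held 7 lower and 2 higher genes, and 0 passed adjusted over the list alone.

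Activity-regulated genes deviated together between rats on average, though not every member did. That each rat's dentate gyrus had been activated to a different degree is a hypothesis for this. The mean pairwise correlation of deviations from the group means among Arc, Fos, Egr1, Homer1, Bdnf, Nr4a1, Junb and Fosb was 0.204, at percentile 99.53 of 10000 random sets of similar expression, whose 95th percentile was 0.111. With 1 array left out the percentile stayed between 97.55 and 99.75. Junb had a Pearson r of -0.32 with Homer1, -0.26 with Fosb and -0.15 with Fos. With Arc, Egr1, Bdnf and Nr4a1 its r lay between 0.06 and 0.22. No single pair passed over 28 pairs: Egr1 and Nr4a1 had the highest Pearson r, 0.712 (permutation p = 0.0176, adjusted p = 0.494), with Spearman rho 0.451 (permutation p = 0.146, adjusted p = 0.634). Their r was 0.307 without the 2 arrays farthest from the median, so that pair rests on those arrays. Differences in dissection or timing may give the same pattern and were not tested.

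Several named genes, such as Ttr and Bdnf, had a larger SD in control rats, but this did not extend to the array as a whole. The SD was larger in control rats for 45.5% of the probe sets and in learning rats for the remaining 54.5%, with a median SD of 0.148 and 0.155. Of 100 splits of the arrays, 33 gave as unequal a share, and the highest other split reached 62.4%, so chance may account for the difference.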
